A study of Homo sapiens with 12 samples.

How the data were processed

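Total RNA of 12 cultures of human pluripotent stem cells was amplified from 100 ng and hybridized by the authors to Illumina bead arrays, all 12 on a single chip, so that no chip batch separates the groups. The table used for the main analysis holds, per the file headers, the mean signal intensity and a detection p-value of each of 47316 probes on each array. The intensity values were deposited on a linear scale without background subtraction or normalization between arrays, running from 98.69 to 36168. The detection p-values were deposited beside them and rise in equal steps of 770 negative control probes, which are not used here. The normalized values deposited in the series record are on a log2 scale; how the authors made them is not given in the sources used here, but they differed by at most 0.00496 from the log2 of the quantile-normalized intensities without background correction. Software versions and any removal of outlying beads are likewise not given in the sources used here. The 24 columns with bead numbers and bead standard errors were not used.

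Background was estimated from the detection p-values and corrected with neqc of limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), with an offset of 16, quantile normalization and log2 transformation. The 93 control probes for spiked RNA were left out, and probes with a detection p under 0.01 on at least 2 of the 12 arrays were kept, 21324 in all. Probes were named through the gene identifiers of the deposited annotation, 35667 of them matched to a current gene table, and 3069 tested genes took a current symbol in place of the deposited one (PRAC1 is listed there as PRAC and ARSL as ARSE). Each gene was represented by its kept probe with the highest mean signal over all arrays (3859 genes had more than 1), which left 16494 genes or unnamed probes for testing, 15672 with a symbol. XIST, TSIX and genes of the Y chromosome, 37 in all, were tested with the rest and are not reported.

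Groups were taken from the sample labels: primed control, primed YAP and naive YAP mTeSR (n = 3 each, H9, H1 and IMR-90), naive YAP N2B27 (n = 1, H9) and naive LPA mTeSR (n = 2, H9 and WIBR3). Naive against primed cells was fitted as a contrast of 2 states over 12 arrays, and the other comparisons as contrasts of a single fit of 5 groups, with lmFit and eBayes of limma. P-values were adjusted after Benjamini and Hochberg over the 16494 genes, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene in the text is from limma. The lines pair the arrays of 3 groups: the deviation of each array from its group's mean correlated at 0.175 on average between arrays of the same line (n = 9 pairs) and at -0.087 between different lines (n = 18), so cell line as a fixed block was run as an alternative and is printed beside a result where it changes a call or moves a count by more than 1.5 times. WIBR3 was sampled once, so in the blocked fit it is its own block and carries no information: every blocked LPA contrast rests on the H9 LPA array alone, taken to vary like the other groups, and the blocked naive group on 5 arrays. The N2B27 array was compared with the H9 naive YAP mTeSR array as log2 differences of genes detected on both, without a test.

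The following 26 gene lists were written, with the comparisons and the alternatives, before the data were examined: naive, primed and core pluripotency genes, YAP and TEAD targets, Hippo components, responses to MEK and ERK, Wnt, cAMP and CREB, LIF and STAT3, NODAL and activin, and BMP, markers of mesendoderm, neuroectoderm, trophoblast and amnion, and fibroblasts and feeders, SRF and actin targets, LPA receptors and enzymes, the respiratory chain, glycolysis, cholesterol synthesis, metallothioneins, amino acid and ER stress, DNA methylation, cell cycle, p53 targets and chromatin regulators. Each list was tested in each comparison with camera of limma with a preset correlation between genes of 0.01, adjusted over the 26 lists, and again with a correlation estimated from the list, with fry and with the cell line as block. Members called are counted over all genes and adjusted over the list alone. For N2B27, list medians were set against 10000 random lists of genes matched by signal.

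Genes named in the text were fixed by a rule: in each comparison the 12 called genes with the largest log2 change in each direction whose arrays in one group all lay on the same side of those in the other, or, where fewer than 10 genes were called, the 10 with the smallest p in the blocked fit, with members of the fixed lists and YAP1 besides. For N2B27 the 10 highest and 10 lowest differences were chosen. Some genes chosen by the rule are not reported here. Genes named outside this rule are stated to have been chosen after their values were seen. A gene was taken as detected on an array at a detection p under 0.01. After the results were seen, differences and list medians were also taken with every signal under the lowest detected signal of its array raised to it. All 53 list medians called by camera kept their sign, and 48 kept at least 50% of their size.

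The fit was tested on simulated data with the same groups, 16494 genes and 100 genes changed by 1 or by 2 on the log2 scale. Of these, 75% and 97% were recovered for naive against primed cells, 28% and 81% for the YAP conversion, 31% and 87% for primed YAP against primed control, 11% and 67% for the LPA conversion, 14% and 77% for LPA against YAP, and 2% and 43% for the difference between the conversions, with 5 to 7 false calls. The simulated noise was normal and independent between genes and arrays, with each gene's spread within the groups. Pairing by line, and differences between groups of a state, were left out. The real fit of naive against primed cells takes such differences into its spread, so these rates describe a simpler case. Alternatives left out background correction, raised the offset to 50, took the deposited normalized values, dropped or tightened the filter on dim probes, averaged the probes of a gene or tested every probe, changed the variance model, weighted the arrays, asked for a log2 change of at least 1, fitted only the groups compared, and left out each array in turn. Where this left 1 array in a group, that array was assumed to vary like the other groups. Leaving out the IMR-90 primed control and WIBR3 arrays together was added after the correlations between arrays were seen.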

Results

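Gene expression was measured on 12 bead arrays of human pluripotent stem cells held in the primed or in the naive state, 6 arrays each. Primed cells resemble the epiblast after implantation, and naive cells the epiblast before it. The cells were H9 and H1 embryonic stem cells, an induced pluripotent line made from IMR-90 fibroblasts, and WIBR3, which the series text calls an embryonic line and its own label an induced one. Primed control cells and primed cells labelled as overexpressing YAP, a transcriptional coactivator that the Hippo pathway restrains, were each sampled in H9, H1 and IMR-90 (n = 3 per group). They were grown on irradiated mouse fibroblasts with 8 ng/ml bFGF. Naive cells received PD0325901 (0.5 µM, a MEK inhibitor), CHIR99021 (3 µM, a GSK3 inhibitor), forskolin (10 µM, which activates adenylyl cyclase) and LIF (1 ng/ml). The naive YAP mTeSR group held the same 3 lines (n = 3), the naive YAP N2B27 group held H9 (n = 1), and the naive LPA mTeSR group held H9 and WIBR3 without the transgene and with 10 µM lysophosphatidic acid, a lipid that activates YAP (n = 2). State and medium changed together in every comparison of naive with primed cells, and whether naive cells grew on feeders was not given in the sources used here. Between 15874 and 19710 of 47316 probes (33.6% to 41.7%) were detected per array, and the number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate experiments beyond the cell line, so p-values measure only the spread between these samples.

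The first principal component held 28.7% of the variance and separated the states: the 6 naive arrays lay between 13.7 and 56.6, and the 6 primed arrays between -46.3 and -21.4. The second held 21.3% and set the WIBR3 naive LPA array (64.5), the IMR-90 primed control array (37.8) and the H1 naive YAP array (32.8) apart from the others. The same 3 arrays had the highest medians of 25 measured fibroblast and feeder cell markers, at 1.51, 2.15 and 0.67 log2 units above the mean of the 12 arrays. Across genes, arrays of the same state correlated at 0.942 to 0.983 when primed and 0.918 to 0.974 when naive, and arrays of different states at 0.907 to 0.961.

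YAP1, on chromosome 11, was read by 1 probe. Its log2 signal was 9.71 ± 0.23 (SD, n = 3) in primed YAP and 10.21 ± 0.43 (n = 3) in primed control cells, a difference of -0.50 ± 0.28 (SE, limma adjusted p = 0.998), and it was lower in the primed YAP array of all 3 lines. The position of the probe against the transgene is not given in the sources used here, so a transgene without that part of the transcript would go unseen and the value checks nothing. The groups are therefore named as labelled.

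Naive cells were set against primed cells over all 12 arrays, to ask which genes mark the naive culture whatever the route and the line. The strongest rise was in DNMT3L, a cofactor of de novo DNA methylation used as a naive marker, from 5.19 ± 0.61 to 10.53 ± 1.54 (SD, n = 6 each), a log2 change of 5.34 ± 0.60 (SE, adjusted p = 0.000258). SP5, a transcription factor gene induced by Wnt signals, rose by 4.44 ± 0.38 (3.94e-05), ABHD12B by 4.37, PRAC1 by 3.80, MBNL3, an RNA-binding splicing regulator, by 3.35, TTC29 by 3.22 and ARSL by 3.09. FGF8, LRFN5, TMEFF2, GAD1 and SLC47A1 rose by 2.48 to 2.85. SHISA2, an inhibitor of FGF and Wnt receptor maturation, fell from 11.87 ± 1.05 to 6.75 ± 0.58, a change of -5.12 ± 0.44 (3.94e-05). The homeobox gene HESX1 changed by -4.47, the tryptophan-degrading enzyme gene IDO1 by -4.28, SCG5 by -4.27 and NPTX1 by -4.15. EEF1A2, IGFBP6 and GRPR changed by -3.53 to -3.81. The lens protein gene CRYAA and the netrin receptor gene UNC5A were detected on all primed and no naive arrays, and were at least 22.7-fold and at least 8.64-fold lower (adjusted p = 0.0074 and 6.5e-06). Such a bound sets the mean of the brighter group against, on each array of the other group, the higher of the probe's own signal and the lowest signal among detected probes. The immunoproteasome subunit gene PSMB8 was detected on 1 of 6 naive arrays and was by this rule at least 7.11-fold lower. Other changes here rest in part on signals under detection, and by the same rule DNMT3L, detected on 2 of 6 primed arrays, changed by 5.01, NPTX1, detected on 2 of 6 naive arrays, by -3.48, and PRAC1, detected on 1 of 6 primed arrays, by 3.16. On each gene named in this paragraph all 6 naive arrays lay on the same side of all 6 primed arrays, which the rule that chose the genes requires.

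**Figure D1:**
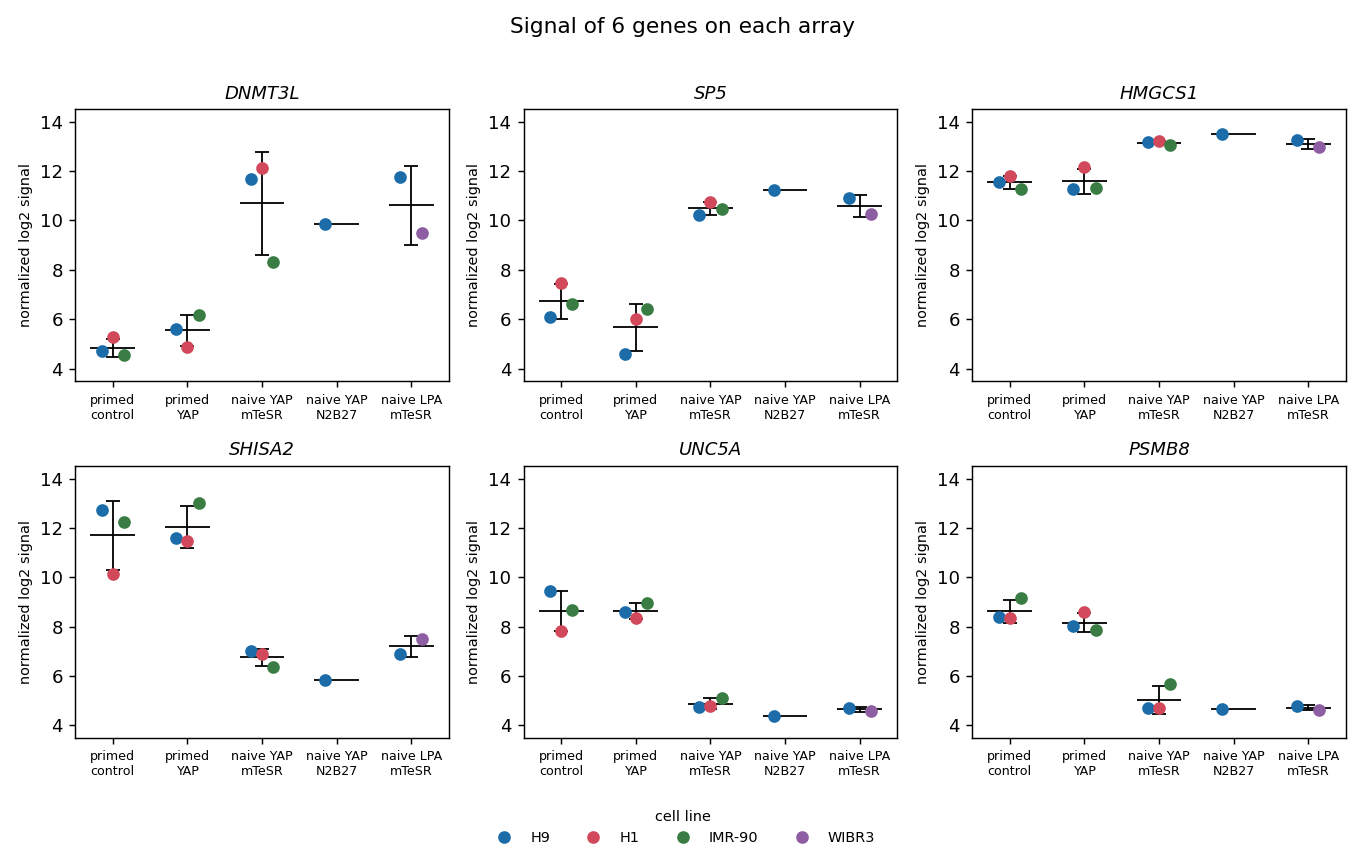
Normalized log2 signal of DNMT3L, SP5, HMGCS1, SHISA2, UNC5A and PSMB8 (vertical axes) on each of the 12 arrays, by group (horizontal axes); each point is an array coloured by cell line, the line is the group mean and the bar 1 SD (none for N2B27, n = 1). In each panel the 6 naive arrays lie wholly above or wholly below the 6 primed arrays, which the rule that chose the genes requires of all but HMGCS1.

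By limma with Benjamini-Hochberg adjustment, 713 of 16494 genes were higher and 859 lower in naive cells (1572 at adjusted p under 0.05), and 616 of them differed at least 2-fold. The count was 908 without the H9 primed control array, 970 without the H9 naive LPA array, 1032 without the IMR-90 primed YAP array and 1041 without the H1 naive YAP array. With array quality weights it was 2993.

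Of 24 measured genes of cholesterol synthesis 20 rose and none fell (21 rose adjusted over the list alone), with a median log2 change of 1.05 (camera adjusted p = 5.69e-22, adjusted p = 0.0169 with an estimated correlation). HMGCS1, the first committed enzyme of the pathway, rose by 1.63 ± 0.17, from 11.56 ± 0.36 to 13.20 ± 0.19 (SD, n = 6), LSS, which makes lanosterol, by 1.60, IDI1 by 1.49 and MVD by 1.48. Of 22 measured Wnt target genes 9 rose and none fell (10 adjusted over the list alone, median 0.93, camera adjusted p = 2.19e-05, adjusted p = 0.611 with an estimated correlation). These were SP5, AXIN2 (1.16), NKD1 (1.84), RNF43 (2.23, at least 2.72-fold), the mesoderm gene TBXT (3.27), WNT3 (2.24), APCDD1, CDX1 and SP8. With the cell line as replicate block APCDD1, CDX1 and SP8 were no longer called (adjusted p = 0.0553, 0.0813 and 0.0568). The Wnt median did not rise on every array. It was -0.35 and -0.52 on the H9 and IMR-90 naive YAP mTeSR arrays, within the range of the primed arrays (-1.11 to 0.10). NODAL itself rose by 3.45 ± 0.68 (adjusted p = 0.00838), and FGF8 was among the genes called of 13 NODAL and activin target genes (3 rose, 5 adjusted over the list alone, median 1.17, camera adjusted p = 0.00204, adjusted p = 0.611 with an estimated correlation). LEFTY1 and LEFTY2 differed by 0.71 ± 0.75 and 1.60 ± 0.63 without passing the test. The NODAL and activin median did not rise on every array either. It was -0.43 on the IMR-90 naive YAP mTeSR array and -0.60 on the WIBR3 array, within the range of the primed arrays (-0.999 to -0.106). Of 10 measured genes of the metallothionein list, which bind metals, 4 rose (5 adjusted over the list alone, median 1.14, camera adjusted p = 0.00285, adjusted p = 0.611 with an estimated correlation): MT1A by 1.22, MT1M by 2.91, MT1F by 2.11 and MT2A by 1.63, the last pair not called with the block (adjusted p = 0.0747 and 0.0511). Metallothionein sequences are close to each other, so a probe may also read a relative.

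**Figure D2:**
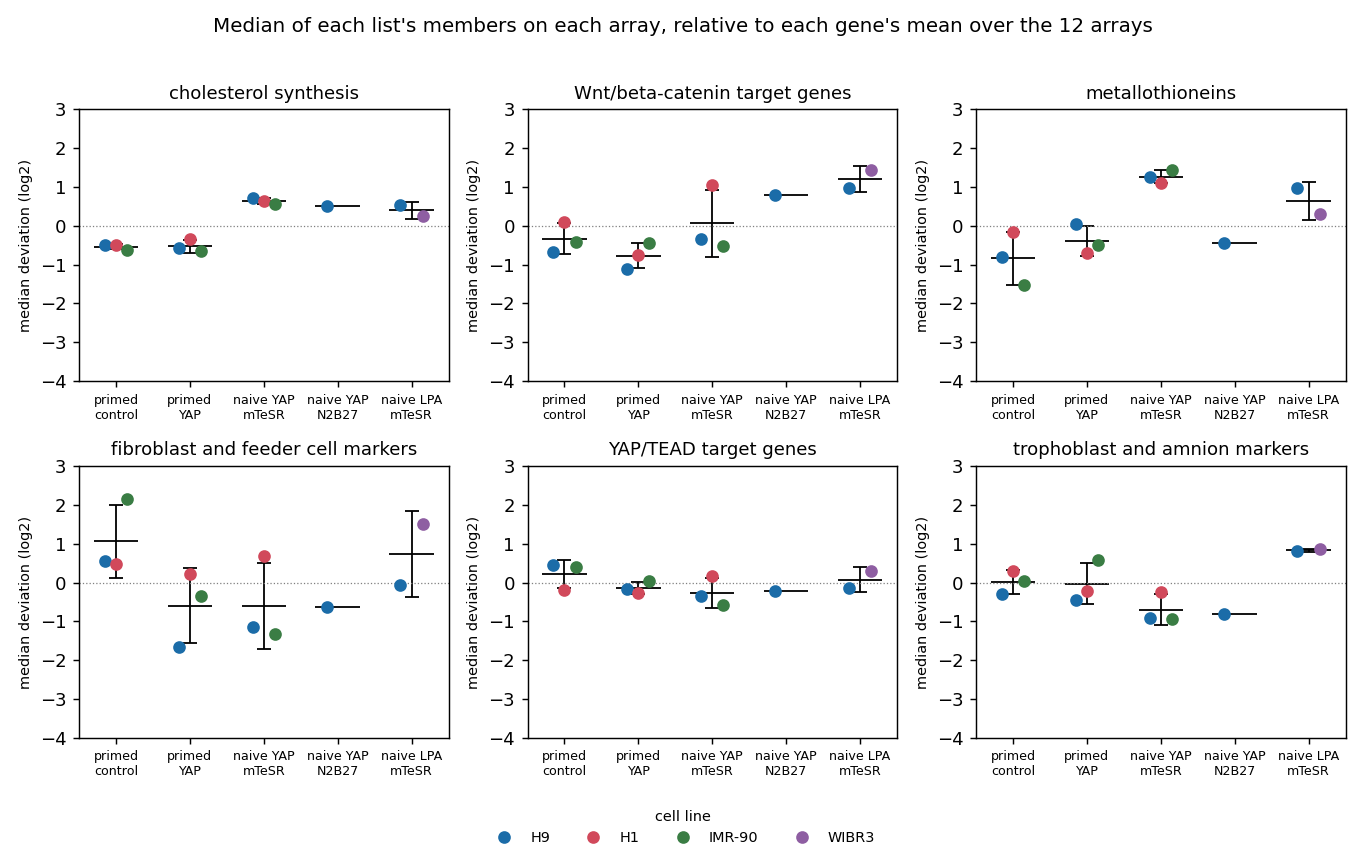
Median over the members of 6 gene lists (vertical axes, log2 deviation from each gene's mean over the 12 arrays) on each array, by group (horizontal axes); points are arrays coloured by cell line, lines are group means and bars 1 SD. Cholesterol synthesis lies above 0 on all 6 naive and below 0 on all 6 primed arrays, and the fibroblast list is highest on the IMR-90 primed control array (2.15) and the WIBR3 naive LPA array (1.51).

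Markers of the naive state did not move together. Of 21 measured, 3 rose (3 adjusted over the list alone) and none fell: DNMT3L, NODAL and GBX2 (1.82, at least 2.35-fold). The list's median was 0.39 (camera adjusted p = 0.0722, adjusted p = 0.0311 with the cell line as replicate block, and 0.764 with an estimated correlation). KLF17, ESRRB, ARGFX, KHDC1L, HORMAD1, MAEL, OOEP and SYCP3 were detected on no array. KLF4 differed by -0.66 ± 0.31, KLF2 by 0.39 ± 0.57, TFCP2L1 by 0.43 ± 0.40 and DPPA3 by -0.20 ± 0.58, none past the test. ZFP42 read 9.02 ± 3.53 in naive and 11.12 ± 0.50 in primed cells: it was 4.41 on the N2B27 array, 4.55 on the WIBR3 array and 10.94 to 11.51 on the other 4 naive arrays. Of 25 primed markers 6 fell and none rose (7 fell and 1 rose adjusted over the list alone, median -0.32, camera adjusted p = 0.0109, adjusted p = 0.611 with an estimated correlation). They were OTX2 (-2.11), DNMT3B (-1.39), SALL2 (-1.23), THY1 (-0.82), PTPRZ1 and CD24, the last pair not called with the block (adjusted p = 0.0767 and 0.0582). Of 16 core pluripotency factors SOX2 (-0.87), the telomere protein gene TERF1 (-2.60) and DNMT3B fell (3 adjusted over the list alone, median -0.43, camera adjusted p = 0.00204, adjusted p = 0.611 with an estimated correlation). The median of the core list was -1.06 on the WIBR3 array and -0.29 to 0.07 on the other naive arrays, against 0.00 to 0.45 on the primed arrays. POU5F1 differed by 0.14 ± 0.35 and NANOG by 0.86 ± 0.56, without passing the test.

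No YAP and TEAD target gene (0 of 23, median -0.23) and no Hippo pathway component (0 of 23, median 0.10) was called by limma in either direction, over all genes or adjusted over the list alone. Among 21 MEK and ERK response genes the immediate early genes EGR1 (-2.26) and IER2 (-0.84) fell (3 fell and 2 rose adjusted over the list alone), with a list median of 0.34, and DUSP6 differed by -0.88 ± 0.47 without passing. Of 11 genes of LPA signalling, the receptor gene LPAR6 (1.82) and the LPA-producing enzyme gene ENPP2 (1.29) rose, and LPAR3 (-1.19) and PLPP3 (-1.19) fell (2 and 2 adjusted over the list alone, median -0.43), with ENPP2 and LPAR3 lost in the blocked fit (adjusted p = 0.0576 and 0.0769). Among differentiation markers TBXT and WNT3 rose and HHEX (-1.66) fell of 17 mesendoderm genes (3 rose and 1 fell adjusted over the list alone, median 0.61). FABP7 (2.35) rose and SIX3 (-3.07, at least 4.28-fold) and LHX5 (blocked adjusted p = 0.0701) fell of 16 neuroectoderm genes (1 rose and 8 fell adjusted over the list alone, median -0.89). The neuroectoderm fall rests largely on signals under detection, as its median was -0.335 with these raised to the lowest detected signal. KRT7 (-1.98) was among 2 genes that fell of 21 trophoblast and amnion genes (3 fell adjusted over the list alone, median 0.11, mean -0.23). MMP2 (1.17) rose and THY1 fell of 25 fibroblast and feeder markers (1 rose adjusted over the list alone, median -0.49). DNMT3L rose and DNMT3B fell of 10 genes of DNA methylation (4 rose and 1 fell adjusted over the list alone, median 0.33), and EZH2 (0.58) and KDM6A (0.67) rose and KDM5B (-0.62) and JARID2 (blocked adjusted p = 0.0614) fell of 17 chromatin regulators (3 and 2 adjusted over the list alone, median 0.05). None of these lists was called by camera. With the cell line as replicate block the mesendoderm (adjusted p = 0.0311), neuroectoderm (0.0156) and glycolysis (0.0311) lists were called, with adjusted p = 0.8, 0.764 and 0.8 with an estimated correlation.

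In the remaining lists few genes were called and camera called none. TOP2A (-0.58) and CCNB2 (-0.64) fell of 25 cell cycle genes (2 fell adjusted over the list alone, median -0.18, blocked adjusted p = 0.065 and 0.0568), TPM1 (-0.64) and FHL2 (blocked adjusted p = 0.0713) fell of 22 SRF and actin target genes (2 fell adjusted over the list alone, median -0.16), and SDF2L1 (0.63) rose and PHGDH (-0.58) fell of 25 genes of amino acid and ER stress (1 and 1 adjusted over the list alone, median -0.01, mean 0.00). PDE4D (1.97, blocked adjusted p = 0.0653) rose of 13 cAMP and CREB target genes (1 rose adjusted over the list alone, median 0.36). NDUFA8 (0.39) rose of 36 respiratory chain genes (0 adjusted over the list alone, median 0.06), and AEN (0.57) of 20 p53 target genes (0 adjusted over the list alone, median 0.18). No member of the glycolysis (21 genes, median 0.13), LIF and STAT3 response (16, median 0.20) or BMP target list (12, median 0.20, mean -0.04) was called over all genes, and 1 BMP target rose and 2 fell adjusted over the list alone.

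Naive YAP mTeSR cells were set against primed YAP cells, the same 3 lines before and after the change to naive medium (n = 3 each), to ask what conversion with the transgene changed. SP5 rose from 5.67 ± 0.95 to 10.49 ± 0.27 (SD), a log2 change of 4.82 ± 0.48 (SE, adjusted p = 0.00269). PRAC1 and ARSL were detected on no primed YAP array and were at least 7.58-fold and at least 8.18-fold higher. MBNL3 rose by 3.01, SLC47A1 by 2.96, GAD1 by 2.74 and ACSS2, which makes acetyl-CoA from acetate, by 2.63. DNMT3L (5.16), LRFN5 (3.28), FABP7 (2.85), TTC29 (2.64) and LIX1L (2.60) rose too, but not with the cell line as replicate block (adjusted p = 0.0538, 0.0506, 0.0698, 0.0524 and 0.0682). SHISA2 (-5.28 ± 0.64), SCG5 (-4.61), HESX1 (-4.24), the von Willebrand factor gene VWF (-3.75), BNIPL (-3.60), and GRPR (-3.17) fell, PSMB8 (detected on 1 of 3 naive arrays) was at least 5.85-fold lower, and UNC5A and CPZ were at least 8.55-fold and at least 7.44-fold lower. NPTX1 (-4.91), IDO1 (-3.84) and EEF1A2 (-3.44) fell without the block and not with it (adjusted p = 0.061, 0.0618 and 0.061). The cholesterol list rose again, with 18 of 24 genes (20 adjusted over the list alone, median 1.15, camera adjusted p = 2.86e-23, adjusted p = 0.0183 with an estimated correlation), HMGCS1 by 1.56 ± 0.25 and LSS by 1.67 ± 0.26.

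By camera 11 further lists were called here. Metallothioneins rose (2 of 10 genes, MT2A by 2.38 and MT1A by 1.60, the latter with a blocked adjusted p of 0.084, 7 adjusted over the list alone, median 1.63, camera adjusted p = 4.14e-06, adjusted p = 0.328 with an estimated correlation). NODAL and activin target genes rose as a list (0 of 13, 5 adjusted over the list alone, median 1.72, 0.000195), as did Wnt target genes (2 of 22, SP5 and RNF43, 6 adjusted over the list alone, median 0.70, 0.000691), and for both the adjusted p = 0.547 with an estimated correlation. Glycolysis (median 0.31, 0.00812), mesendoderm (0.97, 0.0142), p53 target (0.29, 0.0269) and naive marker (0.52, 0.0336) lists rose, and neuroectoderm (-1.06, 0.0142), core pluripotency (-0.31, 0.0142) and cell cycle (-0.22, 0.0206) lists fell, each with adjusted p = 0.618 with an estimated correlation. The neuroectoderm fall rests largely on signals under detection, as its median was -0.32 with these raised to the lowest detected signal. The lines differed in several of these lists. The glycolysis median was 0.72 on the IMR-90 naive array and 0.09 and 0.01 on those of H9 and H1. Within IMR-90 the mesendoderm median went from -0.64 in primed to -1 in naive cells, the naive marker median from -0.52 to -0.56, and the Wnt median from -0.46 to -0.52. The primed marker list fell (-0.48, 0.0269, adjusted p = 0.547 with an estimated correlation). Over all genes, DNMT3L was called among the naive markers, TERF1 (-2.63, blocked adjusted p = 0.0647) among the core factors, and FABP7 (up) and SOX3 (-1.90) among the neuroectoderm genes. In the blocked fit the p53 list was lost (adjusted p = 0.0539) and the trophoblast and amnion list fell (0.0449, adjusted p = 0.618 with an estimated correlation). LPAR6 rose by 2.57 and PLPP3 changed by -1.55. YAP and TEAD target genes gave 0 calls of 23 (median -0.24).

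In total 116 genes were higher and 186 lower after conversion with YAP (302), and 191 were called with the cell line as replicate block, 158 of them shared. The count was 79 without the H9, 120 without the H1 and 112 without the IMR-90 primed YAP array, and 113, 137 and 669 without the naive YAP array of the same lines. It was 621 with array quality weights, 124 when only the 6 arrays compared were fitted, and 172 without the IMR-90 primed control and WIBR3 arrays.

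Primed YAP cells were set against primed control cells to see what the transgene changed before conversion. By limma no gene was called (0 of 16494, 512 at an unadjusted p under 0.05 against 825 expected by chance, smallest adjusted p = 0.998). The cell line block gave 0 as well (656, smallest adjusted p = 0.734). The 10 genes with the smallest blocked p included the chemokine gene CXCL1 (5.63 ± 0.32 in primed YAP and 7.72 ± 0.76 in primed control cells, SD, n = 3 each, difference -2.10 ± 0.33, SE), POSTN (-2.17 ± 0.67), DCN (-3.17 ± 1.24), TFF1 (-1.55), SERPINA3 (-1.29), AKR1C2 (-1.62), ARHGAP24 (-1.18), BCHE (-1.17), DENND2D (-0.84) and P2RX2 (0.89). In simulated data of this size, with independent genes and no pairing by line, 31% of genes changed 2-fold and 87% of genes changed 4-fold were recovered. Without the H1 primed control array 1 gene was called, DAPL1 (-3.04, adjusted p = 0.000415), named after its value was seen.

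The fibroblast and feeder marker list differed most between these groups, with no single member past the test. Its median was -1.62 in primed YAP against primed control cells (0 of 25 called, 0 adjusted over the list alone, camera adjusted p = 1.55e-16, adjusted p = 0.469 with an estimated correlation). COL1A1 differed by -1.82 ± 1.13, COL3A1 by -3.23 ± 1.80 and LOX, which crosslinks collagen, by -2.65 ± 0.76. The list's median was -2.58 within H9, -2.57 within IMR-90 and -0.30 within H1. The feeders of primed cells are mouse fibroblasts, and how far the human probes read mouse RNA was not tested. The YAP and TEAD target list was lower in the same comparison (median -0.44, 0 of 23 called, 0 adjusted over the list alone, camera adjusted p = 0.000243, adjusted p = 0.469 with an estimated correlation), and by line its median was -0.28 in H9, -0.53 in IMR-90 and -0.01 in H1. ANKRD1 differed by -1.79 ± 0.98, CCN2 by -0.87 ± 0.71 and CCN1 by -0.53 ± 0.62. Beside this fall in fibroblast markers, camera also called lower medians of the mesendoderm (-0.88, adjusted p = 0.000106), SRF and actin (-0.41, 0.000877), Wnt (-0.40, 0.00167), cAMP and CREB (-0.48, 0.0111), trophoblast and amnion (-0.34, 0.0111) and BMP (-0.33, 0.0132) lists, and a higher median of the cell cycle list (0.33, 3.58e-05), each with adjusted p = 0.469 with an estimated correlation. The IMR-90 primed control array stood apart in the SRF list (1.04 against 0.11 on H9 and -0.20 on H1) and the cell cycle list (-0.33 against 0.14 and 0.07), and within H1 the SRF median was -0.20 in primed control and -0.01 in primed YAP cells. Within IMR-90 the trophoblast and amnion median was higher in primed YAP (0.57 against 0.05), as was the BMP median (0.25 against 0.07). Within H9 and H1 both were lower. With signals under detection raised to the lowest detected one the trophoblast and amnion median was -0.07. In the same way the cAMP and CREB median was -0.21, the mesendoderm median -0.565 and the YAP and TEAD median -0.29. The NODAL and activin list was lower too (-0.68, 0.0113, adjusted p = 0.475 with an estimated correlation).

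Naive LPA mTeSR cells, which carry no transgene, were set against the primed control cells (n = 2 and 3), to ask what conversion with LPA in its place changed. DNMT3L was detected on no primed control array and was at least 38.9-fold higher. The placental steroid enzyme gene HSD3B1 (at least 7.78-fold), FGF3 (at least 5.39-fold), DLEC1 (at least 4.61-fold) and PSG4 (at least 4.01-fold) were likewise undetected in the control. TTC29 (3.88), SP5 (3.86 ± 0.54), MBNL3 (3.69), TMEFF2 (3.40), ARSL (3.08), and the Wnt inhibitor genes APCDD1 (2.90) and NKD1 (2.66) rose. IDO1 (-5.03 ± 0.70), SHISA2 (-4.51), HESX1 (-4.38), IGFBP6 (-4.09), GRPR (-3.90), AASS (-3.14), MATK (-3.13) and SLC16A9 (-3.12) fell, and UNC5A, PSMB8 and CYP4X1 were at least 9.72-fold, at least 9.63-fold and at least 6.19-fold lower. All of these passed limma at adjusted p = 0.0354 or below, and none did with the cell line as replicate block, where the smallest adjusted p was 0.0606. In that fit WIBR3 is its own block and drops out, so the LPA arm is the H9 array alone and the blocked values are no check of the 2 arrays together.

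Of the gene groups, cholesterol synthesis rose with 5 of 24 genes (18 adjusted over the list alone, median 0.85, camera adjusted p = 2.73e-16, adjusted p = 0.0513 with an estimated correlation), among them HMGCS1 by 1.56 ± 0.28 and LSS by 1.58 ± 0.29. Wnt target genes rose with 4 of 22 (8 adjusted over the list alone, median 1.51, 3.41e-07), and metallothioneins as a list (0 of 10, 5 adjusted over the list alone, median 1.46, 0.00092), both with adjusted p = 0.427 with an estimated correlation. Trophoblast and amnion markers rose with 1 of 21, HSD3B1 (3 adjusted over the list alone, median 1.20, 0.0248, adjusted p = 0.531 with an estimated correlation). The core pluripotency (-0.54, 0.00092, blocked 0.346) and primed marker (-0.41, 0.0248, blocked 0.0609) lists fell and the cAMP and CREB list rose (0.64, 0.0464, blocked 0.166), with adjusted p = 0.475, 0.427 and 0.475 with an estimated correlation. The blocked fit, whose LPA arm is the H9 array alone, called the naive marker (0.00276), mesendoderm (0.00127) and NODAL (0.0187) lists instead, each with adjusted p = 0.948 with an estimated correlation. The WIBR3 array had lower medians in the naive marker list (-0.51 against 0.57 on H9) and the NODAL list (-0.60 against 1.00). It also carried the fall of the core list, at -1.06 against -0.03 on H9 and 0.00 to 0.43 on the 3 controls. YAP and TEAD target genes gave 0 calls of 23 (median -0.04).

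In total 71 genes were higher and 89 lower (160), and 0 were called with the block (1772 at an unadjusted p under 0.05), where the LPA arm is 1 array. The count was 36, 77 and 72 without the H9, H1 or IMR-90 primed control array, 23 without the WIBR3 array, 9 when only the 5 arrays compared were fitted, and 5 without both the IMR-90 primed control and the WIBR3 array.

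Both conversions moved many of the same genes. Of the genes called in either, 31 were higher in both (0.499 expected of independent lists of these sizes) and 67 lower in both (1 expected), and 0 went in opposite directions. The comparisons share no array, though both hold arrays of H9, H1 and IMR-90. They do share the estimate of each gene's spread, so a gene with a small spread is more easily called in both. The lists are therefore not independent, and the expected counts are no strict measure of the overlap. Of the 302 genes called with YAP, 299 (99%) had the same sign with LPA. Across genes the log2 changes correlated at a Pearson r of 0.643 and a Spearman rho of 0.545; genes are not independent replicates. With the cell line as replicate block 0 genes were shared, since that fit, with an LPA arm of 1 array, called none with LPA.

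**Figure D3:**
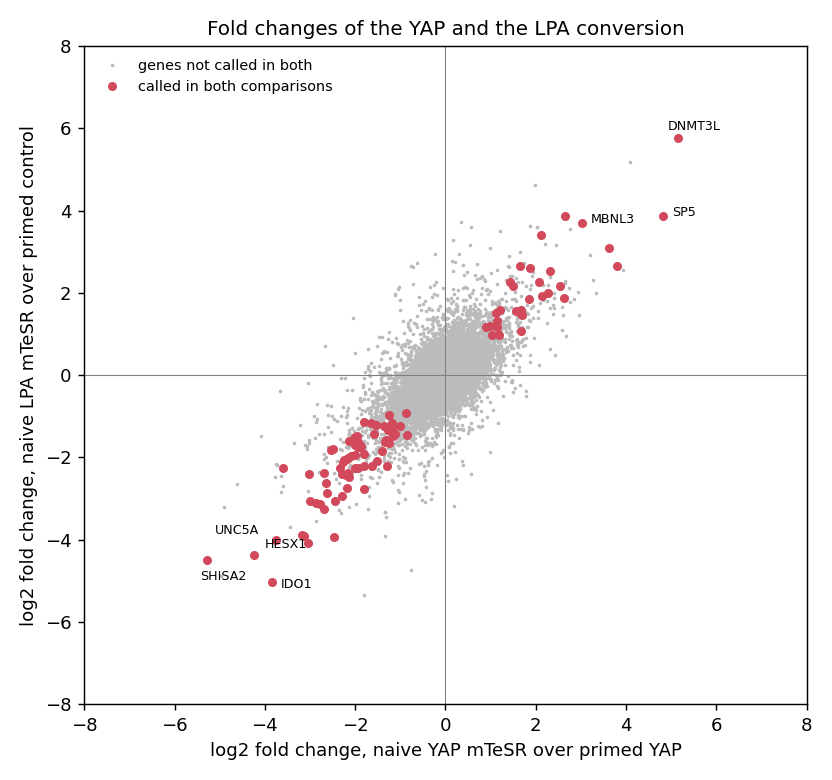
Log2 fold change of each gene in naive YAP mTeSR over primed YAP cells (horizontal axis) and in naive LPA mTeSR over primed control cells (vertical axis); red points are the 98 genes called in both comparisons. Of these, 67 lie at the lower left and 31 at the upper right.

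Whether LPA and YAP gave different naive cells was asked in 2 ways. Naive LPA mTeSR against naive YAP mTeSR cells (n = 2 and 3) gave 0 genes by limma (1612 at an unadjusted p under 0.05, smallest adjusted p = 0.0687), and the difference between the LPA and the YAP conversion gave 0 as well (535, smallest adjusted p = 0.287). With the cell line as replicate block, which leaves the H9 array alone in the LPA arm, 1 gene passed in the first, the chorionic gonadotropin gene CGB5 (6.53 ± 2.49 against 4.52 ± 0.18, SD, blocked adjusted p = 0.0162), whose probe can also read its near-identical relatives. CGB5 was detected on the H9 LPA array and on no naive YAP mTeSR or WIBR3 array, and with signals under detection raised to the lowest detected signal it was 2.60 higher on the H9 LPA than on the H9 YAP array, a lower bound. The other genes with the smallest blocked p were CLEC10A (1.60), FGF3 (3.14 ± 0.40), HSD3B1 (3.38 ± 0.59), NPY (0.61), PROC (1.93), S100P (2.36), CGB1 (1.88), SMG8 (-1.09) and BIK (1.27), none past the test. CLEC10A, FGF3, PROC, CGB1 and BIK were detected on no naive YAP mTeSR array, and were at least 1.61-fold, 4.70-fold, 2.47-fold, 2.23-fold and 1.37-fold higher. Without the filter on dim probes, and with a stricter one, 2 genes were called, CCR7 (1.44) and C11orf87 (1.93). The count was 43 without the H9 naive LPA array, 7 without the WIBR3 array, 6 without the WIBR3 and IMR-90 primed control arrays, and 4 without the IMR-90 naive YAP array (CRABP1, OLIG3, EGR2 and C11orf87, named after their values were seen). For the difference between conversions it was 10 without the H9 naive LPA array, and 1 without the H1 primed control array (DAPL1) or the WIBR3 array (CGB5).

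Trophoblast and amnion markers were higher as a list with LPA than with YAP (median 1.81, 0 of 21 called, 6 adjusted over the list alone, camera adjusted p = 2.53e-10, adjusted p = 0.224 with an estimated correlation). Against the mean of the 3 naive YAP mTeSR arrays, 17 of the 21 were at least 2-fold higher on the H9 LPA array and 11 on the WIBR3 array, 10 of them on both. Many of these probes were under detection on the YAP arrays, and with such signals raised to the lowest detected signal the 3 counts were 13, 11 and 9 and the median was 1.23. On that scale, which gives lower bounds, CGA (5.40), HSD3B1 (3.88) and HAND1 (3.01) led on the H9 array and HAND1 (4.57), IGFBP3 (3.99) and EPAS1 (3.94) on the WIBR3 array. HAND1 does not separate LPA from YAP, as it was 13.31 on the H1 naive YAP array and 13.53 on WIBR3. The fibroblast markers were higher in the same comparison (median 1.15, camera adjusted p = 4.27e-05, adjusted p = 0.556 with an estimated correlation), and beside them the Wnt (1.02, 4.46e-05, 0.405), BMP (1.11, 0.000275, 0.405), neuroectoderm (0.72, 0.000735, 0.556), cAMP and CREB (0.99, 0.000936, 0.399), SRF and actin (0.32, 0.016, 0.649), ER stress (0.21, 0.0228, 0.556), Hippo (0.12, 0.0372, 0.399) and YAP and TEAD target lists (0.24, 0.0372, 0.649), where each bracket gives the median, the camera adjusted p, and the adjusted p with an estimated correlation. With signals raised in the same way the Hippo median was 0.01, the neuroectoderm median 0.43 and the BMP median 0.69. The H1 naive YAP array lay above the H9 LPA array in the Wnt (1.06 against 0.96) and BMP medians (0.475 against 0.462). It did so too in the cAMP and CREB (0.41 against 0.16) and the YAP and TEAD medians (0.17 against -0.14). Like HAND1, these lists therefore do not separate LPA from YAP on every array. Cholesterol synthesis (-0.26, 0.00382, 0.472), glycolysis (-0.32, 0.016, 0.649) and metallothioneins (-0.53, 0.0323, 0.556) were lower. With the block, again with H9 alone in the LPA arm, the YAP and TEAD (0.104), cholesterol (0.104), glycolysis (0.812) and metallothionein (0.294) calls were lost and the mesendoderm list was called higher (3.39e-05, adjusted p = 0.72 with an estimated correlation). In the difference between conversions camera called the trophoblast and amnion (median 1.42, adjusted p = 4.08e-06, adjusted p = 0.654 with an estimated correlation), glycolysis (-0.33, 0.00166), cholesterol (-0.27, 0.00167), NODAL (-0.96, 0.00752) and neuroectoderm (0.80, 0.0279) lists. The neuroectoderm median of this difference was 0.34 with signals raised as above. On the H9 LPA array alone, which the blocked fit rests on, the trophoblast list was called (8.06e-13), and glycolysis (0.366), cholesterol (0.0794), NODAL (0.366) and neuroectoderm (0.111) were not. That fit added the Wnt list (0.0268, adjusted p = 0.784 with an estimated correlation). The adjusted p with an estimated correlation was 0.654 for cholesterol and 0.784 for the other 3.

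Naive H9 cells with YAP were also grown in N2B27, and this array was compared with naive H9 YAP cells in mTeSR; with 1 array each there is no replicate check and no test. Of 11565 genes detected on both, 455 were at least 2-fold higher and 335 at least 2-fold lower in N2B27, against 359 and 205 between the H9 LPA and H9 YAP arrays in mTeSR. The heart and extraembryonic mesoderm factor gene HAND1 was 4.59 log2 units higher (11.38 against 6.78), APLNR 4.24, MSX1 4.07, the Wnt inhibitor gene DKK1 3.82, CPS1 3.80, CSAG1 3.74, COL5A2 3.44 and IFI6 3.38. The H1 naive YAP array in mTeSR lay above the N2B27 array in HAND1 (13.31), APLNR (13.01 against 10.60), MSX1 (11.33 against 9.91), DKK1 (10.88 against 9.55) and COL5A2 (11.51 against 10.33), so these genes do not separate the media across lines. The same holds for IFI6, at 10.17 on the IMR-90 mTeSR array and 9.43 in N2B27. CHCHD2 and CHCHD2P2, which share sequence, were 3.42 and 3.60 higher. The metallothionein gene MT1E differed by -6.86 (6.65 against 13.50), NLRP7 by -4.41, KIF1A by -4.39, TYSND1 by -4.38, the zinc transporter gene SLC39A8 by -4.35, CRMP1 by -4.29, RPL39L by -4.11, KRTCAP3 by -4.06 and MT1P3 by -4.04. The median of the metallothionein list was -1.93, below all 10000 random lists of the same size and signal, with 8 of 10 genes at least 2-fold lower. The NODAL (-1.09) and naive marker (-0.58) lists also lay below all 10000 random lists, and the Wnt list (0.84) above all of them. Other mTeSR arrays went further the same way as N2B27, with a Wnt median of 1.06 on H1 (0.80 in N2B27), and NODAL and naive marker medians of -0.43 and -0.56 on IMR-90 (0.78 and 0.09 in N2B27), so these lists do not separate the media across lines either. The neuroectoderm (0.50, 6 of 16 genes at least 2-fold higher) and primed marker (0.33) lists lay above 99.99% and 99.97% of the random lists. They do not separate the media across lines either. On the IMR-90 mTeSR array their medians were -0.24 and 0.05, above those in N2B27 (-0.36 and -0.07). Without background correction, and in the deposited normalized values, 347 genes differed 2-fold in place of 790.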

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

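In this part the fibroblast covariate and the sample splits were set before their results were seen, and the other tests were chosen, or had their bounds changed, after the result was seen. The first bounds for the tests in the deposited normalized values left both patterns undecided, and a camera p under 0.05 in the same direction was taken as the bound after that. The bound for the test within H9 had been met and was then made stricter.

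For each named gene and list, the 6 naive and the 6 primed arrays were searched for an array far from the rest, by its gap to the next array over the whole range. This ratio passed Dixon's critical value of 0.625 in 49 of 367 groups, where chance gives about 18.4 (1 in 20 groups). The genes include ones chosen for their difference on the N2B27 array or, through the blocked fit, on the H9 LPA array, so the excess over chance is partly set by that choice, and these arrays hold 8 and 7 of the 49. The ratio is given in brackets below.

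The H9 naive LPA array stood above the other naive arrays in CGA (0.811, with a signal of 10.93 against 4.63 to 5.82), CGB1 (0.885), CGB5 (0.890), ENPEP (0.660), KRT7 (0.766) and S100P (0.713) and below them in SMG8 (0.833). The WIBR3 naive LPA array was lowest in DNMT3B (0.827), FDPS (0.649), POU5F1 (0.627, 10.72 against 12.16 to 13.02) and the median of the core pluripotency list (0.676), and highest in CPZ (0.731) and SERPINA3 (0.672). Among naive YAP mTeSR arrays, H9 was lowest in CHCHD2 (0.799) and CHCHD2P2 (0.767), which share sequence, so the rise of both in N2B27 rests on a low value on that array. In CHCHD2 (9.56 there) the H9 primed YAP array was low too, at 9.34 against 11.995 to 12.92 on the other primed arrays. Among the H9 YAP arrays only N2B27 (12.98) was not low in CHCHD2, and the cause was not tested. H1 was highest in CYP4X1 (0.825) and lowest in PHGDH (0.661) and SOX2 (0.630). IMR-90 was lowest in AXIN2 (0.649) and CCN1 (0.692) and highest in the glycolysis list (0.678), PSMB8 (0.867) and TOP2A (0.722). The N2B27 array was lowest in CRMP1 (0.675), KIF1A (0.675), MT1E (0.794), MT2A (0.687), RPL39L (0.627) and TYSND1 (0.784) and highest in CSAG1 (0.781) and PRAC1 (0.630).

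Among primed control arrays, H9 was lowest in ABHD12B (0.651) and highest in DHCR7 (0.648). H1 was highest in CDX2 (0.723), CYP4X1 (0.633) and PRAC1 (0.821). IMR-90 was highest in FHL2 (0.679), KRT7 (0.705), LIX1L (0.649) and the SRF and actin list (0.752), and lowest in the cell cycle list (0.696). Among primed YAP arrays, H9 was lowest in ANKRD1 (0.670), CHCHD2 (0.741) and COL3A1 (0.661) and highest in EGR2 (0.631) and NANOG (0.643), H1 was lowest in GAD1 (0.700), and IMR-90 was lowest in the LIF and STAT3 list (0.712) and highest in PSG4 (0.878).

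The LPA and the YAP conversion differed, by a camera test of the difference itself, in the medians of the trophoblast and amnion (1.42), glycolysis (-0.33), cholesterol (-0.27), NODAL (-0.96) and neuroectoderm (0.80, or 0.34 with signals under detection raised to the lowest detected one) lists. With an estimated correlation none of the 5 was called (adjusted p = 0.654 to 0.784), and the blocked call of the trophoblast list rests on the H9 LPA array alone, the array that stood apart in CGA, CGB5, KRT7 and ENPEP.

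Fibroblast and feeder markers were lower in primed YAP than in primed control cells (median -1.62, 25 genes). The IMR-90 primed control array, which stood apart, was not the whole cause, as the median was -1.03 without it. A smaller share of fibroblast-like or feeder cells may lie behind it and stays open: 92% of the members were lower in H9 and 96% in IMR-90, but 64% in H1, where COL1A1 was higher in primed YAP (12.53 against 12.04). The most abundant members were TAGLN, COL1A2 and COL1A1, at 14.27, 14.29 and 14.13 on the IMR-90 primed control array and 12.53, 11.23 and 11.28 on its primed YAP partner. Of the 25 genes 15 were detected on all 6 primed arrays and 3 belong to another list, no sort is stated in the labels, how far the probes read RNA of the mouse feeders was not tested, and an effect of YAP on matrix genes stays open as well.

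YAP and TEAD targets were lower in primed YAP cells than in primed control cells, although YAP is labelled as overexpressed. Background correction was not the whole cause, as the median was -0.24 in the deposited values, which lack it (camera adjusted p = 0.00012, limma), while normalization, by quantiles in both, was not varied. With the mean of the fibroblast list on each array as a covariate the median of the 23 genes went from -0.44 (SD 0.86 between members, 18 lower) to -0.023 (SD 0.45, 12 lower), so a share of fibroblast-like cells is a candidate explanation. The camera call ended because the shift itself went, as the members also came closer to each other. The lists share 0 genes, 16 of the 23 targets were detected on all 6 primed arrays, and whether YAP also changed the fibroblast genes cannot be read from this test.

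Trophoblast and amnion markers were higher with LPA than with YAP. Background correction was not the whole cause, as the median of 1.81 became 0.80 in the deposited values, which lack it (camera adjusted p = 8.52e-09, limma), while normalization, by quantiles in both, was not varied. A difference between cell lines cannot be told apart from an effect of LPA: the median within H9, the only line in both groups, was 2.22 (1.28 with signals under detection raised to the lowest detected one), but from 1 array each, and WIBR3 has no YAP partner. Cells leaving the pluripotent state in the LPA cultures could give the same values, and this was not tested. The arrays differed in the genes that led, with CGA at least 5.40 higher on H9 and 0.29 on WIBR3, and ISL1 at least 1.47 and 3.52 higher.

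Chance as the source of the 1572 genes called between the states was weighed by splits of the 12 arrays into 6 and 6. Of 100 drawn from 462, 1 split, the real one, called as many, and the highest other called 281. This met the bound set before, a share under 0.05. The splits treated the arrays as interchangeable and did not keep the cell lines, which pair them, so chance is made less likely and not excluded. For the YAP conversion (302 genes, highest other 0) and for primed YAP against primed control (0 genes, highest other 0) the 10 splits of 6 arrays are too few for a share under 0.05. Of these, 4 part all 3 lines, as the real one does, and the highest other among them called 0 in both comparisons.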

How the results depend on the processing

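Leaving out the IMR-90 primed control and the WIBR3 array together, and YAP1 under other processing, were alternatives chosen after the data were seen; all others were planned. Between naive and primed cells 1572 genes were called, 2993 with array quality weights, 616 with a log2 change of at least 1, and 908 to 1960 with 1 array left out. For the YAP conversion the 302 calls became 621 with array weights, 191 with the cell line as replicate block, 124 with only the groups compared, 172 without both arrays standing apart, and 79 to 669 with 1 array left out. For the LPA conversion the 160 calls became 0 with the block, which leaves 1 array in the LPA arm, 9 with only the groups compared, 5 without both arrays, and 23 to 131 with 1 array left out. Primed YAP against primed control gave 0 under every setting but 1 array left out (0 to 1). LPA against YAP gave 0 and then 2 without the filter on dim probes, 2 with the stricter filter, 1 with the block, 6 without both arrays, and 0 to 43 with 1 array left out. The difference between conversions gave 0 to 10 with 1 array left out and 0 otherwise. The 98 genes shared by the conversions became 0 with the block, which called none with LPA, and were 90 in the deposited values, 90 without background correction and 91 with a log2 change of at least 1.

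For N2B27 against mTeSR 790 genes differed 2-fold, 347 in the deposited values, 347 without background correction and 615 against the mean of the 3 naive YAP mTeSR arrays. Without background correction the background stays in both values and draws their ratio toward 1. Of 156 list tests 53 were called, 2 with an estimated correlation, 10 with fry, 51 with the block and 56 in the deposited values. Cholesterol synthesis in naive against primed cells and in the YAP conversion were the 2 called with an estimated correlation. Asking for a log2 change of at least 1 lowers a count by construction. For the other shifts the cause was not tested.

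Of 4990 values of the chosen genes under the alternatives, 4262 stayed on their side of the threshold, 709 kept their direction and were no longer called, 19 became called and 0 reversed. In comparisons with a test, direction was checked only where a gene was called in the main fit or in the alternative. For naive against primed cells the fits without the N2B27 and without the WIBR3 array are counted more than once. Of the losses 66 came without both arrays standing apart, 64 with the block and 55 with only the groups compared. The block changed no call of a named result other than those printed beside it. YAP1 in primed YAP against primed control was -0.50, -0.45 in the deposited values and -0.45 without background correction, with adjusted p from 0.98 to 0.998 over these and the block.

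Signal over background limits genes near the detection level: 33.6% to 41.7% of probes were detected per array. A change in such a gene can be compressed, or can rest on signals under detection. Only differences and folds taken against the lowest detected signal are lower bounds.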

Other observations

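Both hypotheses in this part were found and tested on the same data, and both tests were chosen after the result was seen. Besides PSMB8, genes named in the next paragraph were chosen after their values were seen.

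PSMB8, TAP1 and TAP2, genes of antigen processing, were lower in naive than in primed cells. PSMB8, a subunit of the immunoproteasome, was detected on 1 of 6 naive arrays and was at least 7.11-fold lower. The peptide transporter gene TAP1 changed by -2.47 and TAP2, detected on 0 of 6 naive arrays, was at least 2.79-fold lower (limma adjusted p = 0.00128 and 0.000117). HLA-B (-1.89), TAPBP (-1.23) and B2M (-1.11) lay on the same side without passing the test, and ERAP1 (0.05), TAPBPL (0.05), ERAP2 (0.09) and HLA-E (0.12) lay slightly above 0. A list of 19 genes of this class, written after PSMB8 was seen, had 17 measured, 3 called lower, 0 higher and a median of -0.77 (camera p = 1.59e-05 and 0.061 with an estimated correlation of 0.241, limma). A fall that may cover the class and not single genes therefore stays open, since PSMB8 was itself the reason for the list and 3 of 17 were called.

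HAND1 took 2 levels among the naive arrays. It was 11.38 or more on 4 of them, the H1 naive YAP, N2B27, H9 LPA and WIBR3 arrays, and 6.78 or less on the H9 and IMR-90 naive YAP mTeSR arrays. The hypothesis was that it may go with fibroblast-type genes, and across the 6 naive arrays it correlated with the mean of the fibroblast list at r = 0.886 (exact permutation p = 0.0278 over 720 orders) and rho = 0.943. A gap of 4.59 in a range of 6.75 splits the arrays, so r restates that split and decides nothing. A test over all 12 arrays had been set first and met its bound. It was replaced after that, because the arrays fall into 2 states.

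ZFP42, a marker that both states usually express, was at 4.41 on the N2B27 array and 4.55 on the WIBR3 array. CRABP1 was at 9.50 and 9.76 on the H9 and H1 naive YAP mTeSR arrays and at 11.48 to 14.34 on the other 10. Both genes were singled out after their values were seen.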
